A study of Mus musculus with 8 samples.

How the data were processed

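Gene expression was measured by RNA sequencing in 8 libraries of splenic B cells from C57BL/6 mice: 3 of naive B cells, 3 of cells stimulated with CpG and 2 of cells that also received LPS, PMA and ionomycin. Per the labels' protocols, total RNA was taken with a column kit and DNase digestion, and libraries were made with polyA selection and a strand-specific kit. Per the submitters' processing notes, STAR, HTSeq and edgeR were used with build mm9, with no versions given. The annotation release is not given in the sources used here. The deposited values are raw counts per gene, 1 file per library, and the names of the files say that the counting ignored strand. Each file held 37583 gene identifiers and 5 summary lines, which were set apart from the genes.

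Gene totals were 18815323, 20069272 and 19158547 in naive replicates 1 to 3, 15804311, 18871443 and 18255205 in CpG replicates 1 to 3, and 17550712 and 19431042 in TLR replicates 1 and 2. A single count was worth 0.0498 to 0.0633 CPM, and where a group had 3 or fewer counts for a gene, the change is given as a bound from 3 counts over the group or as a ratio of counts with an exact interval. Changes given after leaving out a library are fitted values, and for genes with few counts they can rest on fewer counts than this. Reads aligned to several places made up 14.7% to 50.2% of all lines, reads in no gene 7.84% to 15.0%, and ambiguous reads 1.29% to 2.15%. Genes with close copies, such as Gapdh, Ccl3, Ccl4 and the Ifit, Oas, class II and immunoglobulin genes, may therefore be counted only in part. How many reads each of them lost was not measured. Symbols and biotypes came from the GENCODE M21 reference by identifier, which matched 32860 identifiers and left 4723, holding at most 1.01% of the counts of any library. Because counting ignored strand, exons of the 133 genes named by rule were compared with those of other genes: 16 overlapped another gene, 15 of them on the opposite strand (among them Bcl3, Cd180, Ciita, Dnajb9, Gapdh, H2-DMa, Irf5, Itga4, Nfkb2, Pfkp, Shisa3, Slc2a1 and Spns2) and Pdia4 on the same strand.

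Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (13964 genes), scaled by TMM, and fitted by quasi-likelihood over all 8 libraries with a mean for each group (common dispersion 0.0421). The 3 comparisons were CpG against naive, TLR against CpG and TLR against naive. Genes were called at an adjusted p below 0.05 (Benjamini and Hochberg over all tested genes), fold changes used a prior count of 0.125, and the SE is the log2 fold change divided by the square root of the F statistic. CPM values were scaled with the same factors. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over 25 lists: 16 programmes (regulatory B cell genes, B cell identity, plasma cell programme, cell cycle, cytokines and chemokines, immediate early genes, NF-kB targets, interferon-stimulated genes, antigen presentation, glycolysis, cholesterol synthesis, unfolded protein response, Toll-like receptor pathway, immunoglobulin genes, trafficking receptors, apoptosis and survival) and 9 other cell types (T, natural killer, macrophage and monocyte, dendritic, neutrophil, basophil and mast, erythroid, platelet, stromal and endothelial). Of the listed genes, 5 were not found by symbol (Bcl2a1a, Bcl2a1d, Hmgcs1, Igha and Ighd). Whether they are present under identifiers that were not matched to a symbol was not examined.

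The groups, comparisons, main tests, naming rule and most alternatives were fixed before the data were examined. Genes named by rule were the 5 highest and 5 lowest called genes with a mean of at least 8 CPM, no overlap between the groups' libraries and an established symbol, up to 4 called members of each programme list by smallest p (2 if none was called), and Il10, Ebi3, Il12a, Tgfb1, Havcr1, Cd274, Cd1d1, Cd5 and Tlr9. Members listed to explain a count of a list, and levels given to follow a named gene into another comparison, were named after the calls were seen. Results for some genes that the rule names are not reported here. Replicate numbers were not treated as pairs in the main analysis, since the labels do not pair the libraries. Replicate 1 of each group carries another library prefix than the others, and the prefix was examined as a term and by restricting to the 5 other libraries.

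Alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter, a mean of at least 1 CPM, only the 2 groups compared, the replicate number as a block, the prefix as a term, only the libraries with the common prefix, immunoglobulin genes left out, an estimated correlation in camera, and each library left out in turn. For lists, both prefix alternatives were chosen after the data were seen. The pipeline was tested on simulated data with 13964 genes, of which 200 were changed. That is far fewer than were called in the real data, so the rates may not carry over. Of 50 genes changed 2-fold, 60%, 54% and 48% were called for CpG against naive, TLR against naive and TLR against CpG. Of 50 changed 4-fold, 82%, 78% and 80% were called. Unchanged genes called numbered 8, 12 and 7, and none of 20 unchanged lists was called. The simulated genes varied independently of each other, so this result does not carry over to lists whose members vary together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.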

Results

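RNA was sequenced from B cells isolated from the spleens of C57BL/6 mice, in 8 libraries that fall into 3 groups. The naive group had 3 libraries of naive B cells. The CpG group had 3 libraries of B cells kept for 3 days with CpG ODN1668, a synthetic DNA oligonucleotide that activates the endosomal receptor TLR9. The TLR group had 2 libraries of B cells given the same CpG culture with LPS (a TLR4 ligand), PMA (an activator of protein kinase C) and ionomycin (a calcium ionophore) added for the final 5 hours. The series title calls both treated populations Bregs, that is regulatory B cells, which are known for secreting the cytokine IL-10. The values are counts of reads per gene. The gene counts summed to 18815323, 20069272 and 19158547 in naive replicates 1 to 3, 15804311, 18871443 and 18255205 in CpG replicates 1 to 3, and 17550712 and 19431042 in TLR replicates 1 and 2, so that 1 count was worth 0.0498 to 0.0633 CPM, the unit of depth-scaled counts used throughout. Levels below are means ± SD in CPM over the 3 naive, 3 CpG or 2 TLR libraries, and log2 fold changes carry ± SE. CPM values are shares of each library and not amounts per cell.

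The group was the main source of variation. In a principal component analysis of log2 CPM, component 1 (65.8% of the variance) placed the naive libraries between -106 and -91.5, the CpG libraries between 29.6 and 38.3, and the TLR libraries at 96.2 and 89.1. Component 2 (18.5%) separated the CpG libraries (-52.7 to -48.1) from the TLR libraries (55.5 and 49.2). Component 3 (5.66%) separated replicate 1 of each group from the other replicates. Replicate 1 of each group also carried another library prefix (RCa1) than the others (RCa18), a difference whose meaning the labels do not give, so values within each prefix are given for the counts of genes. The labels do not say that replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries.

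The comparison of CpG with naive cells asks which genes 3 days with CpG changed. Il10, the gene of the cytokine that defines regulatory B cells, rose from 0.466 ± 0.409 CPM in naive libraries to 50.7 ± 8.60 CPM in CpG libraries, a 108-fold change (log2 fold change 6.75 ± 0.34, edgeR adjusted p = 1.18e-06; 7.73 without naive replicate 1). Every tested gene of the cell cycle list rose, as did 16 of the 17 tested genes of cholesterol synthesis, while 14 of the 18 tested genes of antigen presentation and co-stimulation and 11 of the 23 tested genes of mature B cell identity fell. Cr2, the complement receptor CD21, fell from 1413 ± 94.3 to 104 ± 39.5 CPM. Fcer2a, the low-affinity IgE receptor CD23, fell from 1215 ± 185 to 63.8 ± 21.1 CPM. Markers of other blood cells were lower as well, with summed natural killer cell markers at 78.6 ± 44.8 CPM in naive and 4.32 ± 0.822 CPM in CpG libraries. In all, 6347 of 13964 tested genes passed the edgeR quasi-likelihood test at an adjusted p below 0.05, 3286 of them higher and 3061 lower in CpG, and 1588 rose and 1505 fell at least 2-fold.

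Among the 23 tested regulatory B cell genes, 8 rose with CpG (Il10, Il12a, Havcr1, Ctla4, Lag3, Cd24a, Cd38 and Nfil3) and 12 fell (Tgfb1, Pdcd1lg2, Fasl, Gzmb, Cd9, Entpd1, Nt5e, Cd1d1, Cd5, Ahr, Maf and Thbs1). Havcr1, which encodes the surface receptor TIM-1, rose from 4.11 ± 0.936 to 37.8 ± 6.30 CPM (log2 fold change 3.20 ± 0.25). Ctla4, an inhibitory receptor best known from T cells, rose from 0.880 ± 0.375 to 28.5 ± 4.31 CPM (5.02 ± 0.26), and Nfil3, a basic leucine zipper transcription factor, from 1.69 ± 0.508 to 44.1 ± 3.29 CPM (4.71 ± 0.26). Il12a, a subunit shared by IL-12 and IL-35, rose from 26.1 ± 2.36 to 79.8 ± 27.4 CPM. Ebi3, the other subunit of IL-35, stood at 10.6 ± 1.72 and 13.4 ± 1.43 CPM (adjusted p = 0.203, or 0.0493 in the RCa18 libraries alone), and Cd274, which encodes PD-L1, at 75.6 ± 8.71 and 75.9 ± 17.4 CPM (adjusted p = 0.987). Cd1d1 and Cd5, surface markers by which IL-10-producing B cells of the spleen are often sorted, fell from 78.1 ± 9.77 to 12.5 ± 2.16 CPM (-2.65 ± 0.26) and from 3.26 ± 0.297 to 0.258 ± 0.194 CPM (-3.60 ± 0.57; -4.40 without CpG replicate 2). Tgfb1 fell slightly, from 372 ± 32.9 to 291 ± 12.8 CPM (-0.35 ± 0.11, adjusted p = 0.0295), and lost the call when naive replicate 2 or 3 or CpG replicate 2 or 3 was left out (adjusted p = 0.0973, 0.113, 0.0527 and 0.0770). Several of the genes that fell, such as Gzmb, Fasl and Cd5, are also known from natural killer or T cells, whose markers fell too. The counts do not tell in which cells these genes fell. The list as a whole was not called by camera, whose direction was up (adjusted p = 0.273), against a median log2 fold change of -0.35 and a mean of -0.36. Tlr9, the receptor for CpG, stood at 162 ± 23.0 CPM in naive and 156 ± 40.0 CPM in CpG libraries (adjusted p = 0.828).

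**Figure D1:**
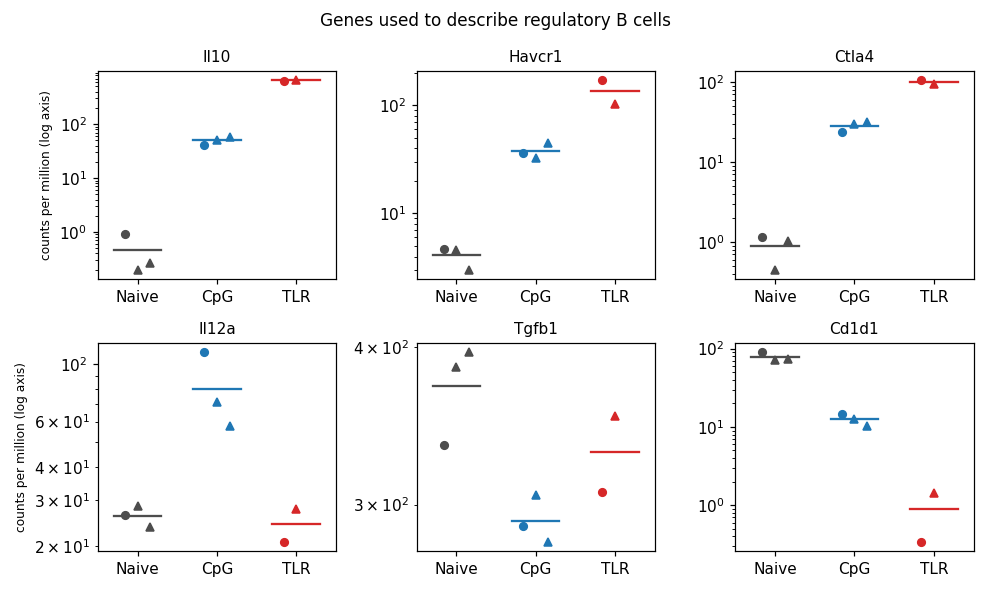
CPM (log axis) of 6 genes used to describe regulatory B cells, with a point for each library (circles, prefix RCa1; triangles, prefix RCa18) and a line at each group's mean. Il10 rises from a mean of 0.466 in naive to 50.7 in CpG and 646 in TLR libraries, Il12a is highest in the CpG libraries, and Cd1d1 falls from 78.1 to 12.5 and 0.893.

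Genes of cell division and of lipid synthesis rose together with CpG. All 26 tested cell cycle genes rose (median log2 fold change 2.36, camera adjusted p = 1.08e-18; adjusted p = 0.332 with an estimated correlation). Tyms, which encodes thymidylate synthase, rose from 4.50 ± 0.316 to 73.4 ± 23.3 CPM. Rrm2, a subunit of ribonucleotide reductase, rose from 18.2 ± 1.65 to 226 ± 82.1 CPM, and the mitotic kinase gene Aurkb from 16.1 ± 1.80 to 89.9 ± 22.3 CPM. Cholesterol synthesis followed with 16 of 17 genes higher and none lower (median 2.30, camera adjusted p = 2.72e-13; adjusted p = 0.342 with an estimated correlation). Sqle, Msmo1 and Mvd, enzymes of the pathway, rose 8.18-fold, 8.23-fold and 8.00-fold. Of 16 glycolysis genes 11 rose and 1, the glucose transporter gene Slc2a1, fell (median 1.39, camera adjusted p = 0.00723; adjusted p = 0.584 with an estimated correlation). Hk2, which encodes hexokinase 2, rose from 17.6 ± 3.99 to 68.9 ± 20.8 CPM. The summed glycolysis genes stood at 5847 CPM in CpG replicate 2 against 2221 and 2511 CPM in CpG replicates 1 and 3, and Ldha rose by 1.58 ± 0.34 on the log2 scale, or by 0.96 without CpG replicate 2.

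Apoptosis and survival genes went up in 9 of 13 tested members and down in 1, Gadd45a (median 0.87, camera adjusted p = 0.00161; adjusted p = 0.322 with an estimated correlation). They included the protective Bcl2a1b (from 4.19 ± 1.43 to 28.8 ± 2.18 CPM) as well as the death-promoting Bbc3, which encodes PUMA (from 5.57 ± 1.42 to 45.7 ± 15.6 CPM). Of the NF-kB target genes 8 of 18 rose and 4 fell (Nfkb2, Rel, Birc3 and Icam1), with a median of 0.15 (camera adjusted p = 0.000173; adjusted p = 0.342 with an estimated correlation). Nfkbiz, a nuclear regulator of NF-kB, rose from 47.0 ± 5.32 to 894 ± 181 CPM, and the activation marker Cd83 from 242 ± 30.7 to 1661 ± 119 CPM. In the unfolded protein response list 6 of 16 rose and none fell (median 0.48, camera adjusted p = 0.00288; adjusted p = 0.342 with an estimated correlation). Its strongest members were Chac1 (log2 fold change 6.60 ± 0.79; 5.84 without CpG replicate 3) and Asns (5.45 ± 0.59; 4.65 without CpG replicate 3), both of which also respond to amino acid shortage.

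The plasma cell programme gave 8 higher genes of 15 (Prdm1, Xbp1, Mzb1, Derl3, Sec11c, Ssr4, Cd93 and Tent5c) and 3 lower ones (Irf4, Sdc1 and Slamf7), with a median of 0.65 (camera adjusted p = 0.0134, or 0.0751 without CpG replicate 2; adjusted p = 0.456 with an estimated correlation). The summed list stood at 2676, 1550 and 1505 CPM in naive replicates 1 to 3 and at 2584 ± 96.5 CPM with CpG, so the groups overlapped. Xbp1, a transcription factor of secretory cells, rose from 150 ± 4.64 to 323 ± 8.05 CPM and Mzb1, a chaperone of antibody assembly, from 204 ± 48.0 to 655 ± 58.3 CPM. Sdc1, the plasma cell marker CD138, and Irf4, a transcription factor that plasma cells require, went the other way. The immunoglobulin list was not called, with a median of -0.01, a mean of 0.81 and a camera direction of up (adjusted p = 0.0677). Ighm rose from 8441 ± 2228 to 13312 ± 298 CPM, and its call was lost without naive replicate 2 or 3 (adjusted p = 0.0973 and 0.100). Ighg1 fell by 1.78 ± 0.49, a call lost without naive replicate 2 (adjusted p = 0.0662), and Ighg2b rose by 3.05 ± 0.75, or by 4.55 without naive replicate 1. The immunoglobulin list was called as higher without naive replicate 1 or 2 (adjusted p = 0.00210 and 0.0103), with the replicate number as a block (adjusted p = 0.0436) and in the RCa18 libraries alone (adjusted p = 0.0105).

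Genes by which B cells present antigen fell with CpG. In that list 14 of 18 tested members fell and none rose (median -1.05, camera adjusted p = 5.28e-08; adjusted p = 0.322 with an estimated correlation). Icosl, the ligand of the T cell receptor ICOS, fell from 515 ± 20.2 to 78.9 ± 11.6 CPM (-2.71 ± 0.19). Cd86, a ligand of CD28, fell from 53.6 ± 10.8 to 11.03 ± 3.23 CPM (-2.27 ± 0.22), and the class II chaperone gene H2-Ob from 1634 ± 105.5 to 477 ± 108 CPM (-1.78 ± 0.18). Macrophages and dendritic cells also express class II genes, and their markers were lower in the CpG libraries. In naive replicates 1 to 3 the summed macrophage markers were 1324, 324 and 177 CPM and the dendritic ones 93.0, 34.0 and 49.8 CPM. The summed antigen presentation list did not follow them, at 32028, 31508 and 32710 CPM, and stood at 18271 ± 3081 CPM with CpG. This argues against loss of these cells as the main source of the fall in the summed list. B cell identity genes gave 11 lower and 1 higher (Bach2) of 23 (median -0.44, camera adjusted p = 3.93e-07; adjusted p = 0.322 with an estimated correlation). Besides Cr2 and Fcer2a, Fcmr, the IgM Fc receptor gene, fell from 1226 ± 169 to 120 ± 22.3 CPM and Blk, a kinase of B cell receptor signalling, from 668 ± 44.0 to 198 ± 22.6 CPM.

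The other programme lists moved in both directions and were not called by camera. Cytokines and chemokines gave 6 higher (Il10, Il6, Csf1, Ccl3, Ccl4 and Vegfa) and 6 lower (Tnf, Lta, Ltb, Ifng, Ccl5 and Cxcl10) of 17, with a median of -1.04, a mean of 0.22 and a camera direction of up (adjusted p = 0.589). Il6 rose from 0.0695 ± 0.0796 to 38.7 ± 13.9 CPM (9.004 ± 0.55; 10.2 without naive replicate 1), values that rest on 4 counts in the naive libraries together. Lta, which encodes lymphotoxin alpha, fell from 54.8 ± 2.73 to 1.23 ± 0.206 CPM (-5.47 ± 0.23). Immediate early genes gave 6 higher and 10 lower of 27 (adjusted p = 0.662), with Atf3 up from 0.706 ± 0.336 to 164 ± 35.8 CPM and Fos down from 167 ± 104 to 3.25 ± 2.25 CPM (-5.71 ± 0.70; -6.35 without CpG replicate 1). Interferon-stimulated genes gave 6 higher and 3 lower of 22 (adjusted p = 0.693), the Toll-like receptor pathway 7 higher and 8 lower of 21 (adjusted p = 0.693), and trafficking receptors 4 higher and 7 lower of 14 (adjusted p = 0.618). Among the last, Cd44, a hyaluronan receptor, rose from 120 ± 16.2 to 871 ± 237 CPM, and Itgb7, an integrin subunit of gut homing, fell from 294 ± 17.7 to 57.0 ± 22.5 CPM.

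Among called genes with a mean of at least 8 CPM over all libraries, no overlap between the groups and an established symbol, the highest fold changes belonged to genes with almost no reads in naive cells. Avpr1a, a vasopressin receptor, had no count in any naive library and 42.0 ± 8.51 CPM with CpG, which is at least 817-fold higher when the naive group is set at 3 counts over the group. Cldn2, a tight junction protein, rose from 0.0862 ± 0.0607 to 87.0 ± 42.2 CPM (9.88 ± 0.58; 10.5 without naive replicate 1). Cdhr2, a protocadherin of the epithelial brush border, rose from 0.152 ± 0.131 to 85.6 ± 18.1 CPM (9.05 ± 0.34; 9.97 without naive replicate 2). Under the same conditions the 5 lowest were Adgre4, Ccr3, Slc40a1, Mertk and Vcam1, which fell from levels that differed widely between naive replicates. Vcam1 is in the macrophage and monocyte list, whose sum was 1324, 324 and 177 CPM in naive replicates 1 to 3. Whether these 5 falls took place in B cells or in other cells was not tested. Vcam1 stood at 332, 86.7 and 41.4 CPM in naive replicates 1 to 3 and at 1.14 ± 0.912 CPM with CpG (-7.08 ± 0.92; -5.83 without naive replicate 1 and -7.80 without CpG replicate 3). Slc40a1, the iron exporter, fell by 7.79 ± 0.95 (-6.47 and -8.57 without the same libraries). Adgre4 had 2 counts in the CpG libraries against 1523 in the naive ones, a ratio of 686 (exact 95% counting interval 190 to 5670; log2 fold change -9.20 ± 1.08, or -8.03 without naive replicate 1). Such an interval covers counting error alone and leaves out the spread between libraries, which was wide here (26.2 ± 25.8 CPM in naive libraries). Ccr3 had 3 against 1242, a ratio of 373 (interval 127 to 1811; -8.39 ± 1.18, or -7.05 without naive replicate 1). All 3 counts lay in CpG replicate 3, so no fold change is given without that library. Mertk fell by 7.78 ± 1.115 (-6.35 and -8.42 without naive replicate 1 and CpG replicate 3).

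Markers of other cell types that a splenic B cell preparation can hold were lower with CpG. All 10 natural killer cell markers fell (camera adjusted p = 2.90e-06; adjusted p = 0.342 with an estimated correlation). Also lower were 11 of 12 macrophage and monocyte markers, with Itgam higher (adjusted p = 0.00183; adjusted p = 0.498 with an estimated correlation), and 8 of 10 dendritic cell markers (adjusted p = 0.00121; adjusted p = 0.342 with an estimated correlation). The same held for 11 of 14 T cell markers (adjusted p = 0.00243; adjusted p = 0.498 with an estimated correlation) and 4 of 5 basophil and mast cell markers (adjusted p = 0.00459; adjusted p = 0.342 with an estimated correlation). Not called as lists were the erythroid (4 of 6 lower, adjusted p = 0.114), platelet (1 of 3 lower, adjusted p = 0.0688), neutrophil (2 of 2 lower, adjusted p = 0.273) and stromal and endothelial (none of 3 called, adjusted p = 0.693) markers. Without naive replicate 2 the erythroid and platelet lists were called as lower (adjusted p = 0.0211 and 0.0203). The erythroid list was also called as lower with the replicate number as a block (adjusted p = 0.0130) and with the prefix as a term (adjusted p = 0.0249). The T cell and basophil lists lost their calls when genes needed a mean of at least 1 CPM (adjusted p = 0.185 and 0.0877). Summed macrophage and monocyte markers were 1324, 324 and 177 CPM in naive replicates 1 to 3 and 71.2 ± 14.4 CPM with CpG. T cell markers overlapped between the groups in their sum (78.7 ± 17.3 and 58.9 ± 14.6 CPM).

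**Figure D2:**
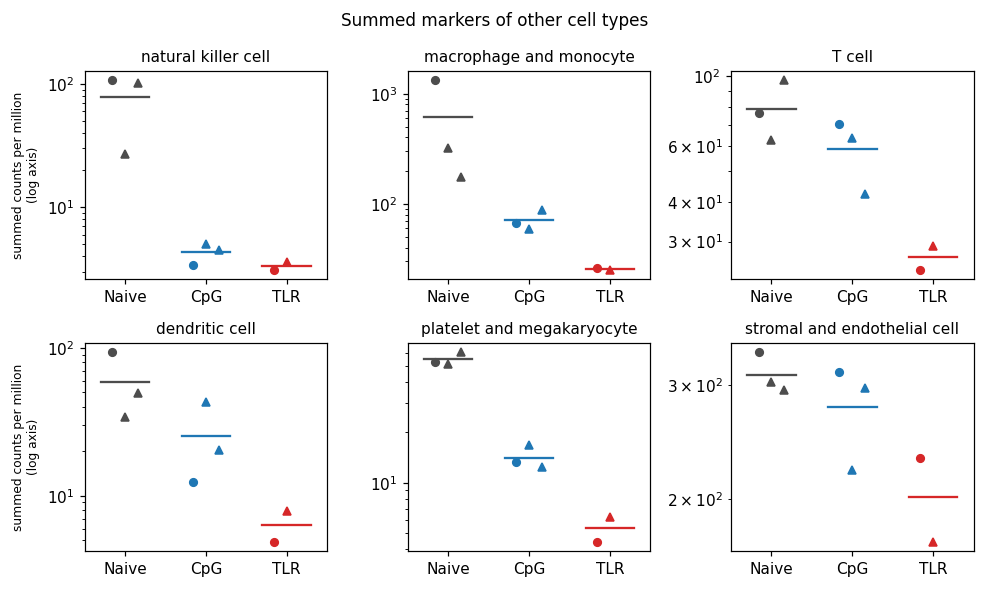
Summed CPM (log axis) of the markers of 6 other cell types, with a point for each library (circles, prefix RCa1; triangles, prefix RCa18) and a line at each group's mean. Natural killer markers fall from a mean of 78.6 in naive to 4.32 in CpG libraries, macrophage and monocyte markers range from 177 to 1324 within the naive group, and T cell markers of naive and CpG libraries overlap.

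Within the prefixes, 6316 of the 6347 called genes (99.5%) had the same direction in the RCa1 pair and in the RCa18 libraries. The genes were called from these same libraries, so such agreement is partly built in. In the RCa18 libraries alone 6808 genes were called. Over all tested genes 56.0% showed no overlap between the CpG and naive libraries, where chance gives 10%. Adjusted over the list alone, the counts above held except for 9 higher regulatory B cell genes, 10 higher plasma cell genes, 7 lower cytokines, 17 higher cholesterol genes, and 12 T cell, 5 basophil and 3 platelet markers lower. In all, 14 of the 25 lists were called with the preset correlation and none with an estimated correlation. The labels do not say whether the naive cells were cultured, and no group labelled as cultured without CpG is analysed here. If the naive cells were not cultured, the effect of CpG and that of 3 days in culture are measured together.

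The comparison of TLR with CpG cells asks what the final 5 hours with LPS, PMA and ionomycin added. Il10 rose a further 12.7-fold, from 50.7 ± 8.60 to 646 ± 9.95 CPM (log2 fold change 3.67 ± 0.25, edgeR adjusted p = 9.39e-06). At the same time 20 of the 23 tested genes of mature B cell identity fell and none rose, among them Ms4a1, which encodes CD20, from 1995 ± 503 to 64.5 ± 17.1 CPM. Genes of antigen presentation (14 of 18) and of the Toll-like receptor pathway (16 of 21) fell, while immediate early genes (14 of 27) and cytokines (9 of 17) rose. Markers of natural killer cells were not called in either direction (4.32 ± 0.822 and 3.34 ± 0.317 CPM summed). The test called 5417 of 13964 genes, 2647 higher and 2770 lower in TLR, of which 1067 rose and 1615 fell at least 2-fold.

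Mature B cell identity had the smallest p of all lists (median -1.60, camera adjusted p = 3.21e-20; adjusted p = 0.118 with an estimated correlation). Besides Ms4a1 (-4.95 ± 0.29), Klf2, a transcription factor of quiescent lymphocytes, fell from 310 ± 34.3 to 7.57 ± 0.538 CPM (-5.35 ± 0.22). S1pr1, the receptor for exit from lymphoid organs, fell from 110 ± 25.2 to 3.81 ± 0.210 CPM (-4.85 ± 0.25), and Blk from 198 ± 22.6 to 42.5 ± 0.896 CPM (-2.22 ± 0.15). The members not called were Cr2 (-0.08 ± 0.27), Bach2 (-0.29 ± 0.13) and Btg1 (-0.34 ± 0.14). The summed list stood at 24504 ± 1120 CPM in naive, 16404 ± 2698 in CpG and 5444 ± 259 in TLR libraries. In the RCa1 pair the median of the list was -1.68 and in the RCa18 libraries -1.39.

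**Figure D3:**
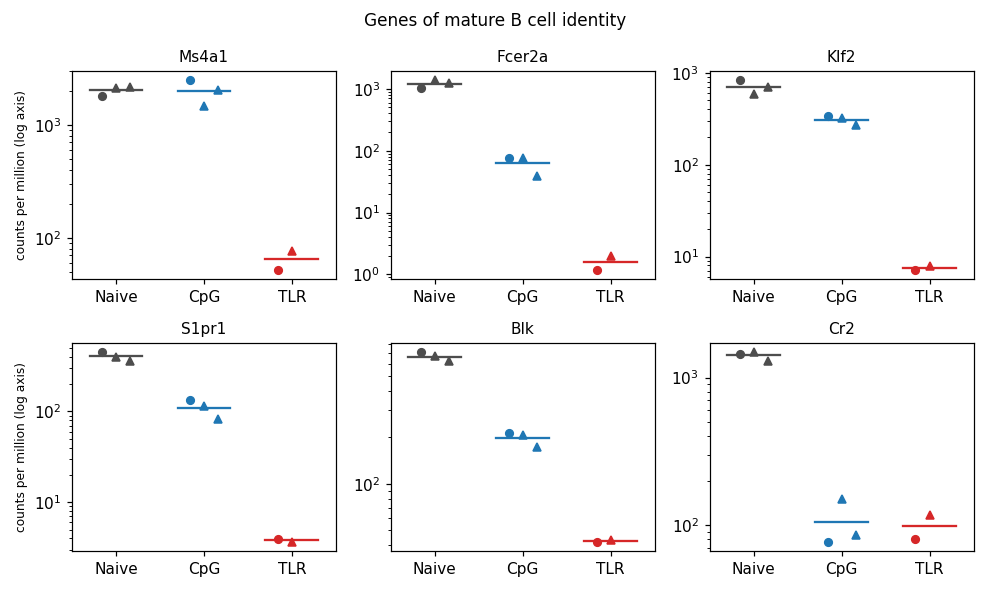
CPM (log axis) of 6 genes of mature B cell identity, with a point for each library (circles, prefix RCa1; triangles, prefix RCa18) and a line at each group's mean. Ms4a1 stays near 1995 with CpG and drops to 64.5 in TLR libraries, Klf2 drops from 310 to 7.57, and Cr2, already low with CpG (104), does not drop further.

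Antigen presentation gave 14 lower and 1 higher (Cd86) of 18 genes (median -1.28, camera adjusted p = 3.34e-08; adjusted p = 0.170 with an estimated correlation). Ciita, the master regulator of class II genes, fell from 257 ± 24.7 to 16.9 ± 2.60 CPM (-3.92 ± 0.17) and the class II gene H2-Ab1 from 1495 ± 207 to 369 ± 51.1 CPM (-2.02 ± 0.17). Cd86 rose from 11.03 ± 3.23 to 98.9 ± 2.38 CPM (3.16 ± 0.23). In the Toll-like receptor pathway 16 of 21 genes fell and none rose (median -0.64, camera adjusted p = 0.000295; adjusted p = 0.170 with an estimated correlation). Tlr9 fell from 156 ± 40.0 to 44.1 ± 8.13 CPM (-1.82 ± 0.23). Tlr4, the LPS receptor, fell from 14.5 ± 4.05 to 2.30 ± 0.112 CPM (-2.66 ± 0.26), and Unc93b1, which carries TLR9 to endosomes, from 1458 ± 215 to 316 ± 18.5 CPM (-2.21 ± 0.17). Trafficking receptors gave 6 lower and 1 higher (Cd44) of 14 (median -0.42, camera adjusted p = 0.00828, or 0.137 with the replicate number as a block; adjusted p = 0.170 with an estimated correlation). Itga4, an integrin subunit, fell from 118 ± 18.2 to 19.0 ± 0.592 CPM.

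Immediate early genes, which respond to calcium and protein kinase C, gave 14 higher and 2 lower (Nfatc1 and Cd69) of 27 (median 1.54, camera adjusted p = 7.75e-06; adjusted p = 0.270 with an estimated correlation). Nr4a1, an orphan nuclear receptor, rose from 50.5 ± 11.2 to 185 ± 25.0 CPM. Egr2 rose from 17.5 ± 2.21 to 54.5 ± 5.23 CPM and the phosphatase gene Dusp4 from 43.6 ± 15.7 to 257 ± 12.8 CPM. Nfatc1 itself fell from 193 ± 35.0 to 54.8 ± 4.26 CPM. Cytokines and chemokines gave 9 higher (Il10, Il6, Tnf, Lta, Il27, Ccl4, Ccl5, Cxcl10 and Vegfa) and 2 lower (Ltb and Csf1) of 17 (median 1.43, camera adjusted p = 0.00737; adjusted p = 0.270 with an estimated correlation). Tnf rose from 6.87 ± 0.938 to 47.8 ± 7.58 CPM, and Ltb, which encodes lymphotoxin beta, fell from 179 ± 65.4 to 10.6 ± 0.457 CPM. NF-kB targets gave 10 higher and 2 lower (Nfkbiz and Birc3) of 18 (median 0.51, camera adjusted p = 0.0237; adjusted p = 0.649 with an estimated correlation). The list lost its call without TLR replicate 1 (adjusted p = 0.130), in the RCa18 libraries alone (adjusted p = 0.131) and with the replicate number as a block (adjusted p = 0.0596). Bcl2l1, which encodes the survival protein BCL-XL, rose from 47.1 ± 4.08 to 172 ± 8.34 CPM. Glycolysis gave 5 higher of 16 and none lower (median 0.81, camera adjusted p = 0.00737; adjusted p = 0.781 with an estimated correlation). Hk2 rose from 68.9 ± 20.8 to 315 ± 53.6 CPM. Within the prefixes the glycolysis median was 1.76 (RCa1) and 0.42 (RCa18), and the list was not called in the RCa18 libraries alone (adjusted p = 0.0553).

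The plasma cell list gave 6 lower (Prdm1, Mzb1, Sec11c, Ell2, Edem1 and Cd93) and 2 higher genes (Irf4 and Sdc1) of 15, with a median of -0.57 (camera adjusted p = 0.0356; adjusted p = 0.649 with an estimated correlation). This call was lost without CpG replicate 1 or 2 or TLR replicate 1 (adjusted p = 0.0533, 0.175 and 0.1046), with the replicate number as a block (adjusted p = 0.0885) and with a mean of at least 1 CPM (adjusted p = 0.0541). Mzb1 fell from 655 ± 58.3 to 139 ± 1.64 CPM, whereas Sdc1 rose from 4.84 ± 3.07 to 30.2 ± 7.04 CPM (2.63 ± 0.38; 3.30 without CpG replicate 2). The immunoglobulin list was not called (camera adjusted p = 0.220).

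Of the regulatory B cell genes 6 rose (Il10, Havcr1, Ctla4, Lag3, Nt5e and Nfil3) and 5 fell (Il12a, Pdcd1lg2, Entpd1, Cd1d1 and Cd38) of 23. The list was not called (camera direction up, adjusted p = 0.791), with a fitted median of -0.35, a mean of -0.08, and a median of 0.18 when genes of 3 or fewer counts in a group are set at 3 counts. Havcr1 rose from 37.8 ± 6.30 to 136 ± 47.7 CPM (1.85 ± 0.24) and Ctla4 from 28.5 ± 4.31 to 99.6 ± 7.90 CPM (1.80 ± 0.21). Il12a fell from 79.8 ± 27.4 to 24.2 ± 4.88 CPM (-1.72 ± 0.27) and Cd38, an NAD-consuming ectoenzyme, from 687 ± 101 to 230 ± 46.3 CPM (-1.58 ± 0.18). Cd1d1 fell from 12.5 ± 2.16 to 0.893 ± 0.782 CPM (-3.77 ± 0.40; -3.10 without TLR replicate 1 and -5.18 without TLR replicate 2). Ebi3 (10.0 ± 2.56 CPM, adjusted p = 0.186), Cd274 (50.1 ± 12.01 CPM, adjusted p = 0.0521) and Tgfb1 (330 ± 32.2 CPM, adjusted p = 0.295) did not pass the test. Cd274 was called as lower with RLE factors (adjusted p = 0.0471), with no low-count filter (0.0236), with the replicate number as a block (0.0378), with the prefix as a term (0.0224), with DESeq2 (0.0224), without CpG replicate 2 (0.0108) and without TLR replicate 1 (0.0439). Ebi3 was called as lower in the RCa18 libraries alone (adjusted p = 0.0413).

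Cell cycle genes gave 6 higher (Mcm2, Mcm3, Mcm5, Mcm6, Mcm7 and E2f1) and 4 lower (Mki67, Ccnb2, Aurkb and Kif11) of 26 and were not called as a list (camera direction up, adjusted p = 0.977, against a median of -0.45 and a mean of -0.17). Mcm5 rose from 232 ± 63.1 to 451 ± 20.6 CPM, Mki67 fell from 269 ± 36.2 to 116 ± 0.529 CPM, and Aurkb fell from 89.9 ± 22.3 to 46.7 ± 5.86 CPM but lost its call without TLR replicate 1 (adjusted p = 0.0535). Camera called none of the remaining programme lists, which were interferon-stimulated genes (5 higher, 3 lower of 22, adjusted p = 0.337), unfolded protein response (5 higher, 4 lower of 16, adjusted p = 0.387), cholesterol synthesis (1 higher, 1 lower of 17, adjusted p = 0.727) and apoptosis and survival (1 higher, 1 lower of 13, adjusted p = 0.804). Interferon-stimulated genes were called as higher without TLR replicate 1 (adjusted p = 0.00036) and in the RCa18 libraries alone (adjusted p = 0.00271). Isg15, a ubiquitin-like protein, rose from 17.3 ± 2.35 to 144 ± 27.7 CPM. Mcl1, a short-lived survival protein, fell from 1515 ± 70.1 to 627 ± 119 CPM, and Atf4, the transcription factor of the integrated stress response, rose from 444 ± 99.0 to 1248 ± 264 CPM.

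Under the conditions on mean, overlap and symbol given for CpG against naive, the highest fold change was that of Epb41l4b, a FERM domain protein, which rose from 0.488 ± 0.398 to 232 ± 57.5 CPM (8.81 ± 0.38; 9.46 without CpG replicate 2). Spp1, which encodes the cytokine osteopontin, rose from 17.5 ± 9.30 to 441 ± 115 CPM (4.65 ± 0.41), and Il1rn, the IL-1 receptor antagonist, from 3.68 ± 3.96 to 79.3 ± 36.6 CPM (4.42 ± 0.71; 5.84 without CpG replicate 3). The lowest under these conditions was Kcnj1, a potassium channel, which fell from 18.1 ± 4.61 to 0.214 ± 0.0624 CPM (-6.34 ± 0.39), followed by Nxpe2, Cacna1i, Spns2 and Klf2. Cacna1i, a calcium channel subunit, fell from 78.5 ± 34.9 to 1.39 ± 0.434 CPM. All 5417 called genes had the same direction within both prefixes, an agreement partly built in because the same libraries made the calls. Without TLR replicate 1 the count fell to 3516. Over all tested genes 59.3% showed no overlap between the TLR and CpG libraries, where chance gives 20%.

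Adjusted over the list alone, the counts for TLR against CpG held except for 21 lower identity genes, 6 lower regulatory genes, 15 higher and 3 lower immediate early genes, 15 lower antigen presentation genes, no higher cholesterol gene, 6 higher unfolded protein response genes, and in the macrophage list none higher and 1 lower. In the basophil list the lower Kit was no longer called. Over all genes, macrophage markers had 1 higher (Fcgr3) and 2 lower (Itgam and Adgre1), dendritic cell markers 1 higher (Zbtb46) and 2 lower (Flt3 and Bst1), and T cell (Lck), platelet (Itgb3) and stromal markers (Cdh5) 1 lower each. The haemoglobin gene Hbb-bt was higher, and the summed erythroid markers stood at 8.26 ± 4.13 CPM in CpG and 35.7 ± 1.497 CPM in TLR libraries. No other-cell list was called by camera. In all, 9 of the 25 lists were called with the preset correlation and none with an estimated correlation. The TLR group holds only 2 libraries, whose spread is estimated together with that of the other groups.

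**Figure D4:**
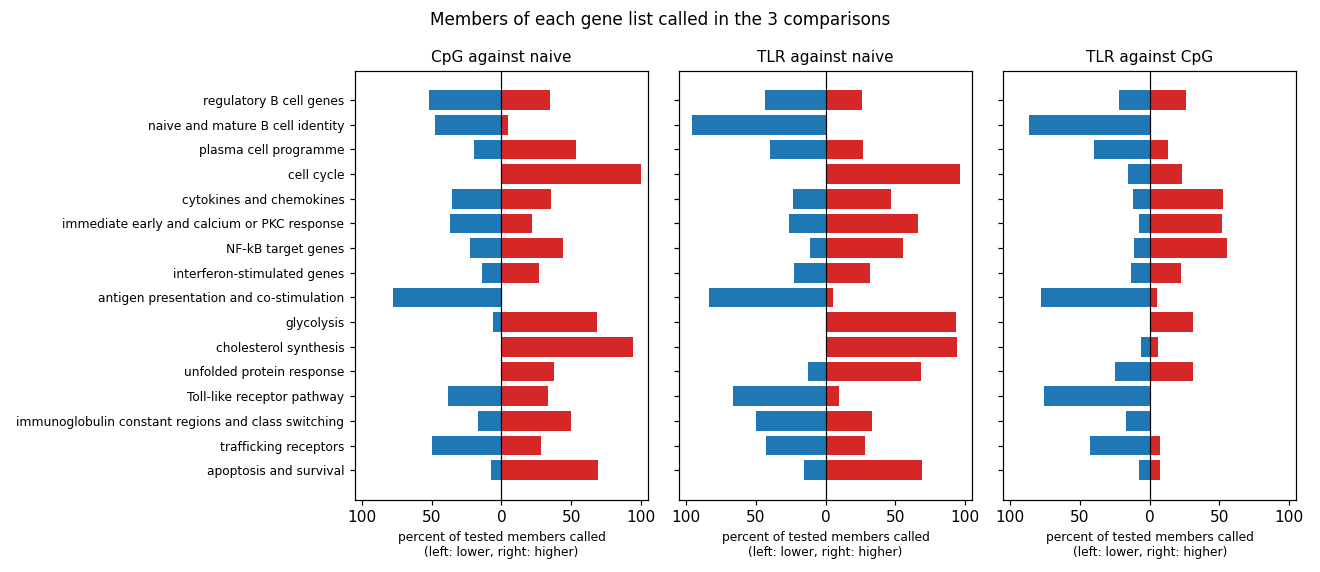
Percent of the tested members of each of 16 gene lists that were called higher (right of 0) or lower (left of 0) at an adjusted p below 0.05, in each of the 3 comparisons. The cell cycle (26 of 26) and cholesterol synthesis (16 of 17) bars lie on the higher side with CpG against naive, and the B cell identity bar (20 of 23) lies on the lower side with TLR against CpG.

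The comparison of TLR with naive cells covers both steps together. Il10 rose from 0.466 ± 0.409 to 646 ± 9.95 CPM (log2 fold change 10.42 ± 0.37, edgeR adjusted p = 1.497e-07; 11.4 without naive replicate 1). Of the 23 B cell identity genes 22 fell, with Fcer2a down from 1215 ± 185 to 1.60 ± 0.583 CPM (-9.55 ± 0.45), and of 18 antigen presentation genes 15 fell and Cd86 rose. Glycolysis (15 of 16), cholesterol synthesis (16 of 17) and cell cycle genes (25 of 26) were higher. Macrophage and monocyte markers were lower in 11 of 12 and natural killer markers in 10 of 10 members. The test called 8551 of 13964 genes, 4409 higher and 4142 lower, and 2571 rose and 2789 fell at least 2-fold.

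Cytokine genes at the top of this comparison had next to no reads in naive cells. Il6 rose from 0.0695 ± 0.0796 to 86.5 ± 29.9 CPM (10.16 ± 0.56; 11.4 without naive replicate 1) and Spp1 from 0.273 ± 0.195 to 441 ± 115 CPM (10.62 ± 0.59). The naive libraries together held 4 counts of Il6 and 16 of Spp1. Shisa3, which encodes a membrane protein that dampens Wnt and FGF signalling, rose from 0.223 ± 0.158 to 790 ± 8.86 CPM (11.75 ± 0.53), and Avpr1a was at least 663-fold higher than the naive group set at 3 counts. Regulatory B cell genes gave 6 higher and 10 lower of 23 (camera direction up, adjusted p = 0.367, against a median of -0.43 and a mean of -0.44). Havcr1 rose 33.0-fold to 136 ± 47.7 CPM and Ctla4 113-fold to 99.6 ± 7.90 CPM. Il12a (-0.11 ± 0.25, adjusted p = 0.719), Ebi3 (-0.08 ± 0.23, adjusted p = 0.790) and Tgfb1 (-0.17 ± 0.13, adjusted p = 0.260) did not pass the test. Cd274 fell from 75.6 ± 8.71 to 50.1 ± 12.01 CPM (adjusted p = 0.0362), a call lost without naive replicate 1 or 2 or TLR replicate 2 (adjusted p = 0.0880, 0.0678 and 0.266) and in the RCa18 libraries alone (adjusted p = 0.0603).

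Among the lists, B cell identity had a median of -2.34 (camera adjusted p = 4.54e-19; adjusted p = 0.126 with an estimated correlation) and antigen presentation one of -2.27 (adjusted p = 3.26e-12; adjusted p = 0.144 with an estimated correlation). Klf2 fell from 706 ± 121 to 7.57 ± 0.538 CPM, S1pr1 from 402 ± 42.8 to 3.81 ± 0.210 CPM. Ciita fell from 525 ± 46.4 to 16.9 ± 2.60 CPM and H2-Ab1 from 3136 ± 90.7 to 369 ± 51.1 CPM. The Toll-like receptor pathway gave 14 lower and 2 higher (Irak2 and Ticam1) of 21 (median -0.97, camera adjusted p = 0.00793; adjusted p = 0.297 with an estimated correlation), with Tlr9 down from 162 ± 23.0 to 44.1 ± 8.13 CPM. Cell cycle genes had a median of 2.07 (adjusted p = 1.12e-09; adjusted p = 0.364 with an estimated correlation), cholesterol synthesis one of 2.45 (adjusted p = 5.19e-08; adjusted p = 0.379 with an estimated correlation) and glycolysis one of 2.16 (adjusted p = 0.000315; adjusted p = 0.438 with an estimated correlation). Bcl2l1 rose 21.2-fold, from 8.10 ± 0.204 to 172 ± 8.34 CPM, and Hk2 17.9-fold, from 17.6 ± 3.99 to 315 ± 53.6 CPM.

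Immediate early genes gave 18 higher and 7 lower of 27 (median 0.97, camera adjusted p = 0.00911; adjusted p = 0.406 with an estimated correlation). NF-kB targets gave 10 higher and 2 lower of 18 (median 0.71, adjusted p = 2.27e-05; adjusted p = 0.297 with an estimated correlation). The unfolded protein response gave 11 higher and 2 lower of 16 (median 0.96, adjusted p = 0.0132; adjusted p = 0.379 with an estimated correlation). Apoptosis and survival genes gave 9 higher and 2 lower of 13 (median 0.95, adjusted p = 0.0157; adjusted p = 0.297 with an estimated correlation). Cytokines gave 8 higher and 4 lower of 17 (median 0.38, adjusted p = 0.0444, or 0.0528 with library size scaling; adjusted p = 0.297 with an estimated correlation). Plasma cell genes (4 higher, 6 lower of 15; median -0.24, mean 0.14, camera direction down, adjusted p = 0.999) and interferon-stimulated genes (7 higher, 5 lower of 22, adjusted p = 0.320) were not called. Neither were immunoglobulin genes (2 higher, 3 lower of 6; median -0.82, camera direction up, adjusted p = 0.650) and trafficking receptors (4 higher, 6 lower of 14, adjusted p = 0.0622). Interferon-stimulated genes were called as higher without TLR replicate 1 (adjusted p = 0.00993) and in the RCa18 libraries alone (adjusted p = 0.0152). Trafficking receptors were called as lower without naive replicate 1, 2 or 3 (adjusted p = 0.0494, 0.0467 and 0.0402) and with the replicate number as a block (adjusted p = 0.0453). The summed genes of the immunoglobulin list stood at 8718 ± 2526 CPM in naive, 14491 ± 245 in CpG and 9989 ± 1722 in TLR libraries.

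Of the other cell types, natural killer (adjusted p = 0.00374; adjusted p = 0.438 with an estimated correlation) and macrophage (adjusted p = 0.0157; adjusted p = 0.551 with an estimated correlation) markers were called as lower than naive. So were dendritic cell (7 of 10 lower, adjusted p = 0.0157; adjusted p = 0.406 with an estimated correlation), T cell (13 of 14 lower, adjusted p = 0.0236; adjusted p = 0.551 with an estimated correlation) and basophil markers (5 of 5 lower, adjusted p = 0.0444; adjusted p = 0.438 with an estimated correlation). The basophil list lost its call without naive replicate 3 (adjusted p = 0.0527), with a mean of at least 1 CPM (adjusted p = 0.163), with the prefix as a term (adjusted p = 0.0635) and in the RCa18 libraries alone (adjusted p = 0.0995). The T cell list lost its call with a mean of at least 1 CPM (adjusted p = 0.228) and in the RCa18 libraries alone (adjusted p = 0.0995). Erythroid (1 higher, 4 lower of 6, adjusted p = 0.367), platelet (2 of 3 lower, adjusted p = 0.0622), neutrophil (1 of 2 lower, adjusted p = 0.431) and stromal markers (2 of 3 lower, adjusted p = 0.286) were not called. Platelet markers were called as lower without naive replicate 1 or 2 (adjusted p = 0.0494 and 0.0298). Adjusted over the list alone, the counts held except for 11 lower regulatory genes, 5 higher and 7 lower trafficking receptors, 2 neutrophil and 3 stromal markers lower.

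In all, 16 of the 25 lists were called against naive with the preset correlation and none with an estimated correlation. Of the 8551 called genes 8549 had the same direction within both prefixes, an agreement partly built in because the same libraries made the calls. Over all tested genes 78.1% showed no overlap between the TLR and naive libraries, where chance gives 20%.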

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

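The test of dilution by other cells was chosen after the results were seen; the other tests were written before. Reads aligned to several places, which no comparison uses, made up a larger share in treated than in naive libraries, and this signal outside the comparisons is why they are listed. The share was 47.1% in CpG replicate 1 and 50.2% in TLR replicate 1, against 37.5% in the naive library with the same prefix. It was 19.9% and 18.1% in CpG replicates 2 and 3 and 21.5% in TLR replicate 2, against at most 15.1% in the naive libraries with the other prefix.

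Markers of natural killer cells, macrophages and other cells were lower in CpG than in naive libraries. A batch marked by the library prefix is argued against, since the macrophage and monocyte median fell by at least 3.48 within each prefix (value -3.48). Every group holds both prefixes, so these values cannot test a batch that follows the groups. Loss of non-B cells from the cultures cannot be told apart from lower expression: the highest median among the cell types was -0.17 (stromal), 4 of 8 types had every CpG library below every naive library, and the sums of T, dendritic, erythroid and stromal markers overlapped. Counts from whole cultures do not separate fewer cells from less of these transcripts per cell.

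Identity genes of B cells fell with LPS, PMA and ionomycin. A few genes taking up the reads would lower the shares of all others alike, by about the list's median of -1.60. This is argued against by a median log2 fold change of -0.00741 (SD 1.15) over all tested genes with library size scaling. A batch marked by the prefix is argued against by medians of -1.68 and -1.39 within the prefixes. A batch that follows the groups was not tested. Dilution by other cells, which lowers all B cell genes by the same factor, is argued against by a range of 5.28 between Klf2 (-5.35 ± 0.22) and Cr2 (-0.08 ± 0.27). The condition first written for that test also asked for a member that was not lower, and 0 members met it, so this reading rests on a limit set after the range was seen. Shares do not measure a change in RNA per cell. A biological loss of these transcripts stays a hypothesis; had transcription stopped for all 5 hours, the falls of Klf2 and Ms4a1 would need half-lives of at most 0.934 and 1.01 hours.

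For CpG against naive, 1 of 10 splits of the 6 libraries, the real one, called as many genes (6347), the highest other split called 0, and 10 splits are too few for a share under 0.05. Every other split mixed naive and CpG libraries, so the difference between the groups widened its spread. A low count there was largely fixed in advance, and no conclusion is drawn from it.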

How the results depend on the processing

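The prefix alternatives for lists were chosen after the data were seen. Counts of genes stayed within 1.5 times the main count in every setting except 1: TLR against CpG called 5417 genes and 3516 without TLR replicate 1. Leaving out each library in turn gave 4888 to 6738 genes for CpG against naive, 6990 to 7948 for TLR against naive and 3516 to 5625 for TLR against CpG, where a lone TLR library is assumed to vary like the other groups. In no setting was a called gene called in the opposite direction.

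With an estimated correlation, camera called 0 lists in CpG against naive, 0 in TLR against naive and 0 in TLR against CpG, from 14, 16 and 9 in the same order. For CpG against naive the estimates lay far above the preset 0.01 in several called lists. They were 0.626 for cell cycle, 0.864 for cholesterol synthesis, 0.886 for natural killer markers and 0.164 for B cell identity. The preset therefore understates how strongly these members vary together. Apoptosis and survival, with an estimate of -0.0333, also lost its call, so a high estimate does not account for every loss. Leaving out a library gave 13 to 17, 16 to 18 and 8 to 9 lists.

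Of 227 named results, 209 kept direction and side of the threshold throughout, 14 lost or gained a call and 4 changed sign. The 4 were all uncalled with log2 fold changes near 0. Cd274 in CpG against naive (0.00) was -0.0330 with RLE factors, -0.0329 with DESeq2, -0.0149 with library size alone, -0.0117 with no filter, -0.0193 with a mean of at least 1 CPM, -0.0181 with the replicate block, -0.00534 with only the 2 groups, and -0.14 to 0.19 leaving out a library. Tlr9 in CpG against naive (-0.06) was 0.0370 with the prefix RCa18 only and -0.26 to 0.11 leaving out a library. Il12a in TLR against naive (-0.11) was 0.0787 with RCa18 only and -0.331 to 0.0868 leaving out a library, and Ebi3 (-0.08) ran from -0.36 to 0.17. The cause was not tested.

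The replicate block gave 6665, 8602 and 5541 genes and 16, 17 and 6 lists. Correlations of residuals between libraries of the same number ran from 0.00359 (naive 3 and CpG 3) to 0.326 (CpG 1 and TLR 1). Number 1 alone has the prefix RCa1, so its pairs share number and prefix. Within RCa18, naive and CpG libraries gave 0.104 and 0.00359 with the same number and 0.00836 and 0.147 with different numbers. TLR replicate 2 gave 0.297 with CpG replicate 2 and 0.0941 with CpG replicate 3. It gave 0.0250 with naive replicate 2 and 0.146 with naive replicate 3. Same numbers were thus not regularly closer, and whether numbers pair the samples stays open. Of simulated genes changed 1.5-fold, 10%, 16% and 10% were called, in data where 200 of 13964 genes were changed.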

Other observations

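The lists and genes in the 2 paragraphs below were chosen after the data were seen. Of 17 genes known to respond to amino acid shortage, 14 were higher and none lower in CpG against naive (median log2 fold change 2.90), and 11 were higher and none lower in TLR against CpG (median 1.49). No enrichment test was made on this list. Asns, which makes asparagine, stood at 1.98 ± 0.547, 86.4 ± 65.3 and 342 ± 111 CPM in naive, CpG and TLR libraries (n = 3, 3 and 2). Psat1, of serine synthesis, stood at 35.2 ± 3.91, 265 ± 124 and 796 ± 222 CPM, Mthfd2, of mitochondrial folate metabolism, at 24.8 ± 2.15, 185 ± 76.0 and 529 ± 161 CPM, and Slc7a5, an amino acid transporter, at 33.0 ± 0.963, 221 ± 134 and 716 ± 285 CPM.

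Of 20 tested transcription factors of B cells, 10 were higher and 5 lower in CpG against naive, and 3 were higher and 9 lower in TLR against CpG. Batf, an AP-1 family factor, stood at 14.0 ± 0.720, 242 ± 31.6 and 489 ± 84.2 CPM, and Cebpd at 0.913 ± 0.653, 202 ± 18.8 and 184 ± 27.4 CPM. Stat5a was unchanged by the test with CpG (53.9 ± 3.99 and 63.7 ± 8.14 CPM) and rose to 632 ± 106 CPM with LPS, PMA and ionomycin (3.31 ± 0.15). Cbfa2t3, a corepressor, fell from 37.0 ± 4.81 to 1.23 ± 0.455 CPM and Ikzf3, which encodes Aiolos, from 334 ± 38.9 to 52.3 ± 11.5 CPM in the same step.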
